A study of Mus musculus with 40 samples.

How the data were processed

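RNA was measured in the number 4 inguinal mammary gland, with its lymph node removed, of Balb/cJ mice whose ovaries were taken out at 21 days of age. After 7 days of recovery the mice received 1 of 3 regimens. These were a purified control diet (AIN 93G), the same diet with 2.7% of it as conjugated linoleic acid (CLA, a set of isomers of an 18-carbon fatty acid), or the control diet with 200 nM estrogen in the drinking water. Estrogen-treated mice and their controls were sampled at 60 h and 84 h, and CLA-fed mice and their own controls at 108 h and 132 h. Each of the 8 groups held 5 mice, described in the labels as biological replicates, so the spread within a group is that between animals.

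Per the labels' protocols, libraries were strand-specific and made from poly(A) RNA with 10 PCR cycles, pooled and run over 4 lanes, from RNA with quality numbers of 7.5 to 9.4 (mean 8.7), at an average of 39 M reads. Per the submitters' processing notes, the genome build was GRCm38. The authors deposited gene counts in 1 table for 60 h and 108 h and another for 84 h and 132 h. The authors deposited RPKM values (reads per kilobase of gene, scaled to the reads of the library) in a matching pair of tables. The aligner, the counting program and the gene model are not given in the sources used here. All 4 tables list 47729 gene symbols, of which 18352 had no count in any library, and every sample column was used.

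The count and RPKM tables were made in different ways. Spearman's rank correlation across genes within a library was 0.903 to 0.916, and in each library 1756 to 2143 genes had counts and an RPKM of 0. Ntm averaged 124700 counts per library and an RPKM of 0.163, while Gapdh averaged 210.5 counts and an RPKM of 25.1. Whether intronic, antisense or shared reads entered the counts is therefore not known, and genes that overlap others or have near-identical copies are less certain than the rest. Among named genes called in a treatment comparison, 0 had count and RPKM fold changes of opposite sign. Most of these genes were picked for a large fold change or small p in the counts, so this says little about other genes.

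Total counts per library, in units of 1e6 counts, ranged from 18.2 to 40.0 (mean 29.3, SD 4.68). No library was a copy of another: over all 780 pairs the lowest chi-square per gene was 12.9, far above sampling noise. Simulated counts with the depths and means of these libraries were used to test the precision. For estrogen at 60 h, with 17382 simulated genes tested, edgeR recovered 46 of 50 genes raised by 1 log2 unit and 39 of 50 lowered by 1, and called 12 unchanged genes. For CLA at 108 h it recovered 43 and 45 of 50, and called 4 unchanged genes. Each simulated group had 200 changed genes of 17852 in all, with equal numbers raised and lowered, and no skin signal was simulated. Changed genes were drawn only from those with an average log2 CPM above 1, so the recovery does not cover genes below that level. The real CLA comparisons called 47.9% and 56.0% of genes, so the simulation does not give the precision at changes that broad.

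Each comparison used edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) on the counts, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and a Benjamini-Hochberg adjusted p threshold of 0.05. A gene is said to rise, fall or change where it passed that threshold. The 4 groups of a table shared 1 estimate of the spread. Differences between times, and controls across the 4 times, used a single fit to all 40 libraries. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are counts per 1e6 after TMM scaling, given as mean ± SD with n = 5 unless stated.

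The 25 gene lists (441 genes), the rule for named genes, the designs and most alternatives were chosen before the data were examined. The rule names, per treatment comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean log2 CPM of at least 1 and all 5 treated libraries on 1 side of the control mean, without predicted genes. It adds the 4 members with the smallest p of each list called by camera, a panel of 15 genes in every comparison, and the 5 largest genes in each direction for differences between effects. The result of 1 gene that the rule names is not reported here. Lists were tested with camera (limma 3.58.1, voom, preset correlation 0.01), again with an estimated correlation, and with fry. Member counts are given over all genes tested and adjusted over the list alone. An exact 2-sided permutation test of the list's mean log2 CPM per library, 5 against 5, was added after seeing the data. Its smallest possible p is 0.0079, which becomes 0.0233 after adjustment over the 100 tests.

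Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter and a stricter filter on low counts, limma on log2(RPKM + 0.1) and log2(RPKM + 1), a fit of the 2 groups alone, the run of animal numbers as a term, and leaving out each library. Leaving out the 9 libraries with the highest skin and hair signal (list mean above 1.5 log2 CPM), and using that signal as a covariate, were added after seeing the data. Animal numbers in the sample titles fall into 4 runs (11 to 43, 78 to 94, 112 to 121 and 138 to 164). The 10 estrogen-treated mice make up the fourth run and no control mouse is in it, so a cohort effect and estrogen cannot be separated. CLA-fed mice and their controls share the other 3 runs. Coordinates are from GENCODE M21 on GRCm38, which held 45127 of the 47729 symbols and 205 of the 206 named genes. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).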

Results

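The 40 libraries formed 8 groups of 5 mice. Mean total counts per group, in units of 1e6 counts, ran from 24.4 ± 4.13 (SD, controls at 132 h) to 33.4 ± 4.20 (estrogen at 60 h). Between 20707 and 22621 genes had at least 1 count in a library. Mitochondrial genes took 5.81 ± 0.70% of counts with CLA at 108 h against 7.76 ± 0.55% in controls, and 5.66 ± 1.60% against 8.59 ± 0.83% at 132 h. With estrogen the shares were 7.68 ± 0.87% against 9.75 ± 0.76% at 60 h and 7.70 ± 1.12% against 8.46 ± 0.12% at 84 h. Genes of skin and hair, a tissue next to the gland, had a list mean of 1.99 to 6.59 log2 CPM in 9 libraries and −1.89 to 1.17 in the other 31. These 9 were 2 controls at 108 h, 3 controls at 132 h, 1 estrogen library at 60 h and 3 at 84 h, and none was from CLA-fed mice.

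Estrogen was compared with the control diet to show the response of the ovariectomised gland to the hormone. Pgr, the progesterone receptor gene and a direct target of the estrogen receptor (chromosome 9, 8899833 to 8968611, plus strand), rose from 1.13 ± 0.75 to 25.8 ± 9.16 CPM at 60 h, a log2 fold change of 4.50 ± 0.57 (SE, adjusted p = 0.000689). At 84 h it rose by 4.88 ± 0.59 (adjusted p = 9.4e-05), with all 5 treated libraries above the control mean at both times. Areg, which encodes the growth factor amphiregulin (chromosome 5, 91139599 to 91148432, plus strand), was close to the limit of detection in controls (0.0257 ± 0.0260 CPM at 60 h) and reached 27.2 ± 10.1 CPM at 84 h. Its log2 fold changes were 8.88 ± 1.35 and 8.94 ± 1.02 (adjusted p = 0.00256 and 7.2e-05). Of 18 estrogen-responsive genes, 7 rose at 60 h and 6 at 84 h and none fell (11 and 10 higher, 2 and 0 lower, adjusted over the list alone). Others that rose were Cited1 (2.37 ± 0.50 and 2.46 ± 0.49) and, at 60 h, the transcription factor gene Myb (1.95 ± 0.39). The list mean went from 2.58 ± 0.42 to 4.15 ± 0.37 log2 CPM at 60 h, and the exact permutation test gave an adjusted p of 0.0233 at both times, the smallest it can give. With camera the list had adjusted p = 0.281 with an estimated correlation at both times. Greb1, another estrogen receptor target, rose by 1.34 ± 0.35 at 60 h and 1.93 ± 0.33 at 84 h. Its 60 h call was lost without any 1 of 7 libraries, all except control replicate 4 and estrogen replicates 2 and 4 (highest adjusted p 0.0805). Esr1, the estrogen receptor gene itself, was at 89.0 ± 5.41 CPM with estrogen and 108 ± 20.3 CPM in controls at 60 h and was not called (−0.28 ± 0.11, adjusted p = 0.132).

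Markers of luminal epithelium, the cells that line mammary ducts, were higher with estrogen: 16 of 21 rose at 60 h and 9 at 84 h, and none fell (20 and 20 adjusted over the list alone). The list mean was 1.34 ± 0.98 log2 CPM in controls and 3.57 ± 0.44 with estrogen at 60 h, and 1.76 ± 1.20 against 4.01 ± 0.36 at 84 h. The exact permutation test gave an adjusted p of 0.0233 at each time, the smallest possible, and camera gave adjusted p = 0.401 with an estimated correlation at both. Among keratins of simple epithelium, Krt7 rose by 2.81 ± 0.55 and 2.64 ± 0.53 and Krt19 by 2.71 ± 0.59 and 2.54 ± 0.53. Krt8 (chromosome 15, 101996698 to 102004482, minus strand) went from 3.47 ± 3.48 to 29.6 ± 14.3 CPM at 60 h, by 3.09 ± 0.71, and rose by 2.69 ± 0.74 at 84 h. The Krt8 call was lost at 60 h without control replicate 4 (adjusted p = 0.0545) or estrogen replicate 1 (0.0519), and at 84 h without any 1 library except control replicate 4 (0.0563 to 0.0934). Other large rises were in the water channel gene Aqp5 (3.13 ± 0.66 and 3.16 ± 0.58) and, at 60 h, in Prom2 (4.07 ± 0.79) and the protease gene Tmprss2 (3.48 ± 0.70). Col9a2 (2.85 ± 0.53) and the transcription factor gene Etv4 (2.60 ± 0.49) were among the 8 genes with the largest rise under the naming rule at 84 h. Wnt4, a paracrine signal of the hormone-responsive gland, rose by 3.54 ± 0.81 at 60 h, and its call was lost without control replicate 3 (adjusted p = 0.0513) or 4 (0.0552).

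Of 15 genes of basal epithelium, the myoepithelial layer, 3 rose at 60 h (11 adjusted over the list alone) and 2 at 84 h (10 adjusted over the list alone). The oxytocin receptor gene Oxtr rose by 1.85 ± 0.35 and 1.55 ± 0.35. The list mean was 1.95 higher at 60 h (exact permutation, adjusted p = 0.0644) and 2.25 higher at 84 h (adjusted p = 0.0233), and camera gave adjusted p = 0.401 and 0.405 with an estimated correlation. Skin shares several of these genes, and 4 estrogen libraries had a high skin and hair signal. Of 7 tested genes for milk proteins and secretory differentiation, 4 rose at 60 h and 1 at 84 h (5 and 1 adjusted over the list alone). Folr1, a folate receptor gene, rose by 2.16 ± 0.36 and 1.92 ± 0.39. The list mean was 1.43 and 1.46 higher (exact permutation, adjusted p = 0.0233), with adjusted p = 0.401 and 0.405 with an estimated correlation. Of 22 mammary growth factor and receptor genes, 4 rose and 2 fell at each time (5 higher and 3 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.279 and 0.587). Its list mean was higher by 0.62 and 0.58 (exact permutation, adjusted p = 0.0233), with Areg and Wnt4 among its members, while the median log2 fold change of its genes was 0.05 and −0.02.

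Cell division genes rose together with estrogen. Of 33, 28 rose at 60 h and 27 at 84 h, and none fell (33 and 31 adjusted over the list alone). The list mean was 0.86 log2 units higher at 60 h, where the exact permutation test gave an adjusted p of 0.102, and 0.98 higher at 84 h (2.49 ± 0.22 against 3.47 ± 0.18, adjusted p = 0.0233). Camera gave adjusted p = 0.401 at 60 h and 0.281 at 84 h with an estimated correlation. At 84 h the mitotic genes Ccnb2 and Plk1 rose by 1.37 ± 0.15 and 1.22 ± 0.13. Mki67, whose product marks cycling cells (chromosome 7, 135689784 to 135716361, minus strand), rose from 24.6 ± 5.53 to 57.2 ± 10.5 CPM at 84 h (1.22 ± 0.22, adjusted p = 0.00258). At 60 h it rose by 1.15 ± 0.33 (adjusted p = 0.0443), with 4 of 5 treated libraries above the control mean. That 60 h call was lost without any 1 of 8 libraries, all except control replicate 1 and estrogen replicate 4 (adjusted p 0.0586 to 0.109).

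Few genes of mature fat cells were called with estrogen. Of 18 mature adipocyte genes, 1 rose at 60 h and none was called at 84 h, where edgeR gave 0 calls also over the list alone. Adipoq, which encodes adiponectin, was at 1254 ± 162 CPM against 1295 ± 44.0 CPM in controls at 60 h (−0.05 ± 0.10). Of 19 fatty acid oxidation genes, 7 fell at 60 h and 1 at 84 h (10 and 4 lower and 1 and 1 higher adjusted over the list alone), among them Acadl at 60 h (−0.41 ± 0.09, adjusted p = 0.0167). The list mean was 0.17 lower at 60 h (exact permutation, adjusted p = 0.344) and 0.29 lower at 84 h (adjusted p = 0.102), and camera gave adjusted p = 0.401 and 0.428 with an estimated correlation. Of 11 brown and beige fat genes, 1 fell at each time (1 and 2 adjusted over the list alone). Their list mean was 0.26 and 0.30 lower (exact permutation, adjusted p = 0.144 and 0.186), and camera called the list lower (adjusted p = 0.00348 and 0.00552, and 0.401 and 0.533 with an estimated correlation). No oxidative phosphorylation gene of 22 was called by edgeR at either time, also over the list alone. Camera called that list lower (adjusted p = 6.38e-07 and 0.00106, and 0.560 and 0.803 with an estimated correlation), with a list mean 0.19 and 0.18 lower (exact permutation, adjusted p = 0.116 and 0.202). The brown fat gene Cidea fell by 0.68 ± 0.14 at 60 h, and Ebf2 fell by 0.50 ± 0.07 at 84 h. Camera also called the fibroblast and matrix list lower at 84 h, with a list mean 0.12 lower (exact permutation, adjusted p = 0.502). That camera call was lost without control replicate 4 (adjusted p = 0.0501) or 5 (0.0512) or estrogen replicate 5 (0.590). No macrophage gene of 17 was called by edgeR at either time, over all genes or over the list alone, and Adgre1 was at 48.8 ± 23.2 CPM against 47.3 ± 15.4 CPM in controls at 60 h. Of 19 interferon-response genes, 0 were called by edgeR at 60 h and 17 were lower adjusted over the list alone, with camera adjusted p = 2e-05 and 0.684 with an estimated correlation. Control replicate 2 at 60 h had an interferon list mean of 6.86 log2 CPM against 3.67 to 4.37 in the other 4 controls. The interferon-induced gene Ifit3b fell by 3.28 ± 0.93 (adjusted p = 0.0447), and by 0.69 without that library (adjusted p = 0.369). The fall of Ifit3b was also not called without control replicate 3 or any 1 of the 5 estrogen libraries (adjusted p 0.0528 to 0.0978).

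In all, 1119 of 17248 genes passed the threshold at 60 h, 702 higher and 417 lower, and 931 of 17180 at 84 h, 592 higher and 339 lower. Upper-quartile scaling gave 920 higher and 288 lower at 60 h and 712 and 231 at 84 h, and limma on log2(RPKM + 0.1) gave 609 and 259 at 60 h and 837 and 140 at 84 h. The 60 h count was lower without control replicate 2 (650), 3 (494) or 4 (436) or estrogen replicate 1 (316), 2 (709) or 5 (448). The 84 h count was lower without control replicate 1 (443), 2 (618) or 5 (591) or estrogen replicate 3 (515) or 4 (548). Without the 9 libraries with a high skin signal the counts were 697 (487 higher and 210 lower) and 303 (281 higher and 22 lower). That left 4 estrogen libraries at 60 h and 2 at 84 h. All 10 estrogen-treated mice came from a run of animal numbers that held no control, so cohort and estrogen were not separable.

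The estrogen effects at both times were set side by side. Among the 16936 genes tested at both, 345 were called at both times against 60.1 for independent lists, all with the same sign, and fold changes had a Pearson correlation of 0.70 across genes, which are not independent replicates. The difference between the effects was called for 1 gene, Gm4876, an antisense transcript that overlaps Tes (chromosome 6, 17065010 to 17171833, minus strand), with 1160 genes at an unadjusted p under 0.05. Gm4876 went from 5.52 ± 0.57 to 11.0 ± 0.97 CPM at 60 h and from 10.6 ± 1.77 to 9.29 ± 0.85 CPM at 84 h, a difference of −1.18 ± 0.19 (adjusted p = 0.00993). DESeq2 called 17 genes. The Gm4876 call was lost in limma on log2(RPKM + 0.1) and without the 9 libraries, which called 0 genes, and in limma on log2(RPKM + 1), which called 1 other gene. Leaving out control replicate 2 of 60 h gave 2.

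**Figure D1:**
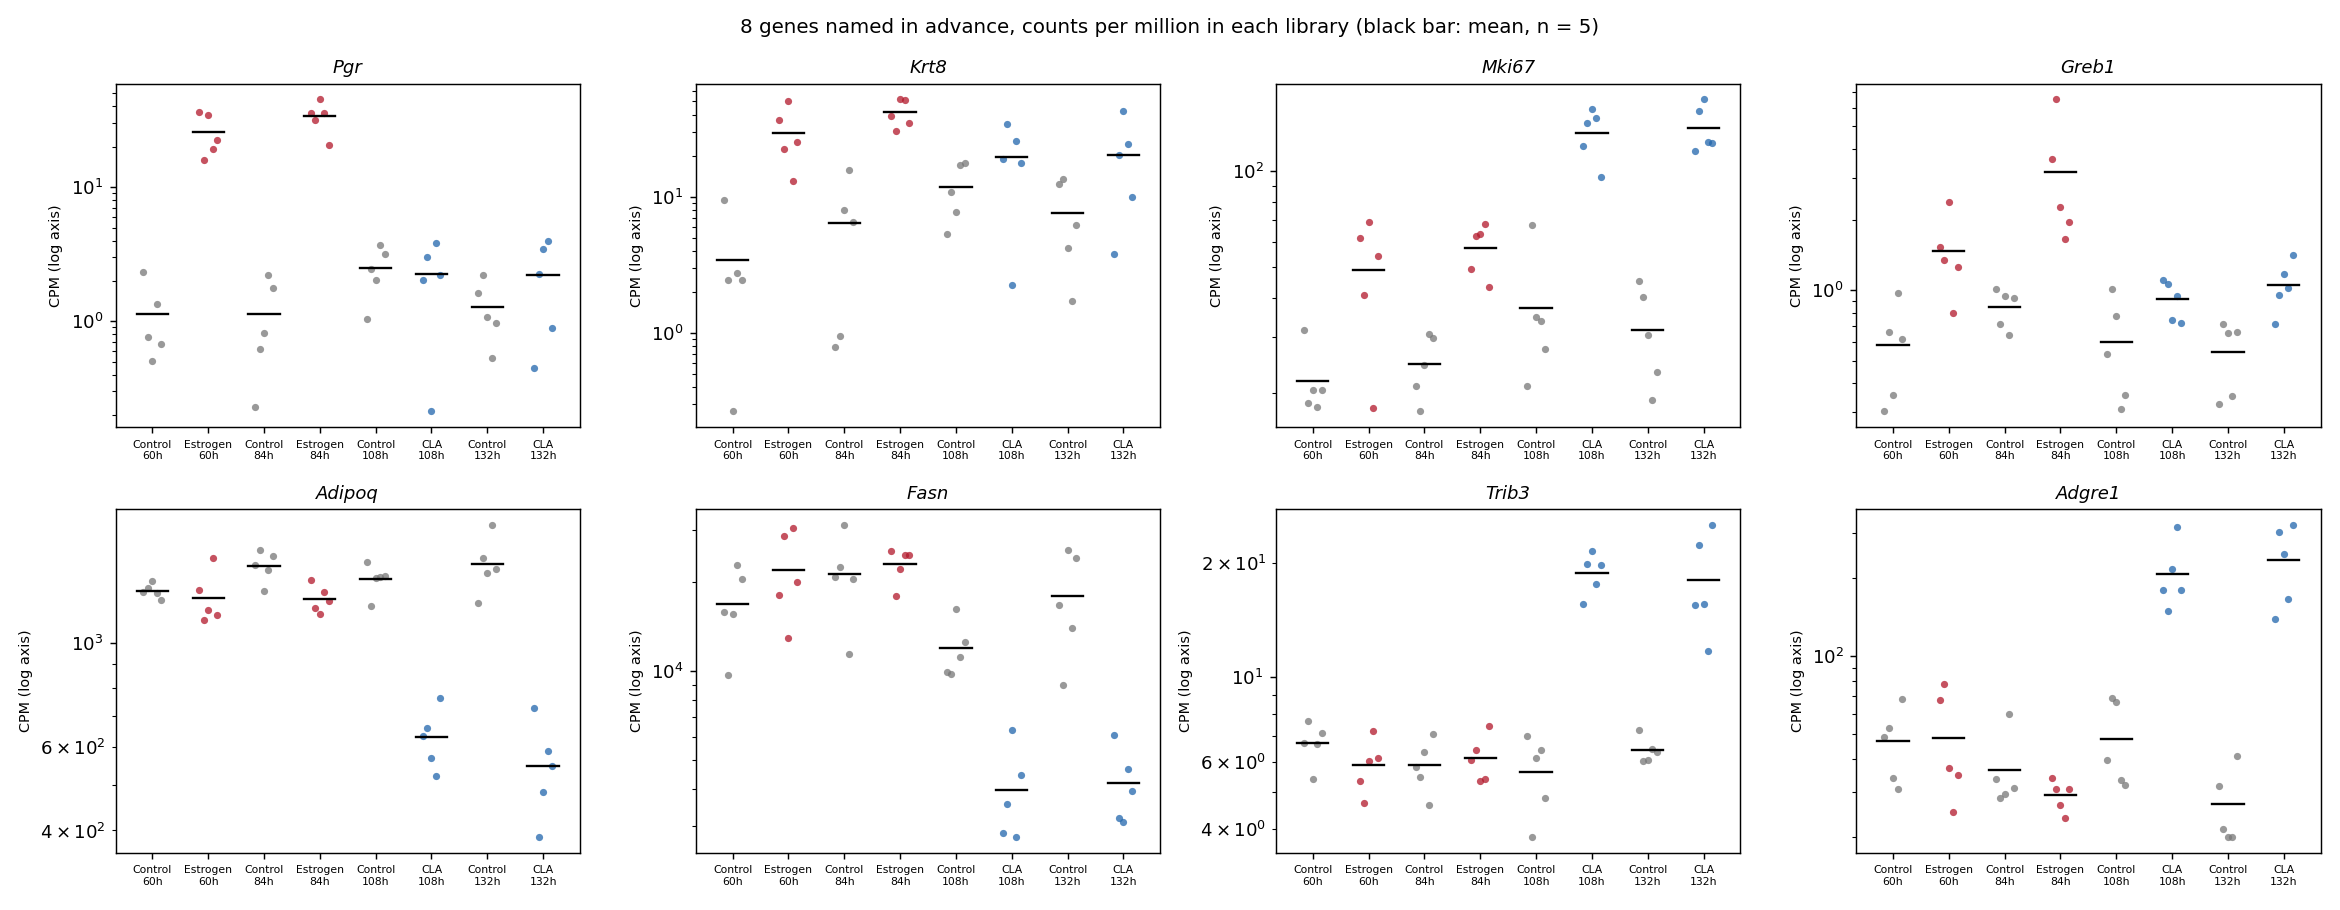
CPM of panel genes (log axis) in each of the 40 libraries, by group, with group means; points are single mice and bars are means of 5. Pgr averaged 25.8 CPM with estrogen and 1.13 CPM in controls at 60 h, and Adgre1 averaged 209 CPM with CLA and 48.4 CPM in controls at 108 h.

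Dietary CLA was compared with the control diet to show its effect in the gland without ovarian hormones. Macrophage genes were higher with CLA. Of 17 tested, 15 rose at 108 h and 16 at 132 h and none fell, with equal counts adjusted over the list alone. The list mean went from 5.72 ± 0.23 to 7.60 ± 0.22 log2 CPM at 108 h and from 5.24 ± 0.29 to 7.81 ± 0.34 at 132 h. The exact permutation test gave an adjusted p of 0.0233 at both times, the smallest possible, and camera gave adjusted p = 0.401 and 0.281 with an estimated correlation. Adgre1, which encodes the macrophage surface protein F4/80 (chromosome 17, 57358691 to 57483527, plus strand), rose from 48.4 ± 18.3 to 209 ± 64.3 CPM at 108 h (2.11 ± 0.34) and from 26.8 ± 9.31 to 233 ± 79.9 CPM at 132 h (3.12 ± 0.28). Trem2, a lipid-sensing receptor of macrophages (chromosome 17, 48346401 to 48354147, plus strand), rose by 4.20 ± 0.35 and 5.20 ± 0.32 (adjusted p = 4.19e-08 and 5.7e-10). The 8 genes with the largest rise under the naming rule were the same at both times. They included Mmp12, which encodes the macrophage elastase, at 5.51 ± 0.64 and 7.48 ± 0.76, the proton pump gene Atp6v0d2 at 5.53 ± 0.44 and 7.27 ± 0.41, Il1rn, Itgax, Adam8, Il7r and Clec12a.

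Genes of fat cells fell with CLA. Of 18 mature adipocyte genes, 15 fell at each time and none rose (16 and 15 lower adjusted over the list alone), and the list mean fell by 0.78 and 1.02 log2 units (exact permutation, adjusted p = 0.0233). Camera gave adjusted p = 0.401 at both times with an estimated correlation. Adipoq (chromosome 16, 23146536 to 23158028, plus strand) fell from 1372 ± 104 to 634 ± 92.3 CPM at 108 h (−1.11 ± 0.10) and from 1461 ± 198 to 540 ± 125 CPM at 132 h (−1.44 ± 0.13). Cfd, which encodes adipsin, fell by 2.48 ± 0.27 at 132 h. Of 22 genes of fatty acid and triglyceride synthesis, 18 fell at 108 h and 19 at 132 h and none rose, with equal counts over the list alone. Their list mean fell by 0.92 and 1.18 (exact permutation, adjusted p = 0.0233), with adjusted p = 0.405 and 0.401 with an estimated correlation. Fasn, the fatty acid synthase gene (chromosome 11, 120805846 to 120824547, minus strand), fell by 1.59 ± 0.27 and 2.11 ± 0.28, and the desaturase gene Scd1 by 1.20 ± 0.16 and 1.61 ± 0.19.

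Mitochondrial and oxidation genes fell as well. Of 22 oxidative phosphorylation genes, 20 fell at 108 h and 21 at 132 h (22 and 21 adjusted over the list alone). The list mean fell by 0.39 (exact permutation, adjusted p = 0.0233) and 0.61 (adjusted p = 0.0441), with adjusted p = 0.546 and 0.636 with an estimated correlation. Sdha fell by 0.64 ± 0.09 and 0.95 ± 0.11. Of 19 fatty acid oxidation genes, 11 fell at 108 h and 14 at 132 h, and 1 rose at each time, with equal counts over the list alone. The gene that rose was Cpt1a, which encodes the enzyme that commits fatty acids to mitochondrial import, by 1.24 ± 0.14 and 1.33 ± 0.14. The list mean fell by 0.28 and 0.58 (exact permutation, adjusted p = 0.0233), with adjusted p = 0.541 and 0.546 with an estimated correlation. Ucp1, the uncoupling protein gene of brown fat, fell by 0.60 ± 0.18 at 108 h and was at −0.33 ± 0.36 at 132 h (adjusted p = 0.460). Of 11 brown and beige fat genes, 4 fell at each time, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.0678 and 0.108). Its list mean fell by 0.34 at 108 h (exact permutation, adjusted p = 0.0233) and was 0.42 lower at 132 h (adjusted p = 0.155).

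Stress-response genes rose with CLA. Of 22 genes of endoplasmic reticulum stress and the integrated stress response, 16 rose and 2 fell at 108 h and 14 rose and 3 fell at 132 h, with equal counts over the list alone. The list mean rose by 0.90 and 0.78 (exact permutation, adjusted p = 0.0233), with adjusted p = 0.281 and 0.441 with an estimated correlation. Atf3, a stress-induced transcription factor gene (chromosome 1, 191170296 to 191218039, minus strand), rose from 6.39 ± 2.81 to 92.6 ± 14.8 CPM at 108 h (3.85 ± 0.27) and by 4.49 ± 0.30 at 132 h. Trib3 rose by 1.74 ± 0.15 and 1.47 ± 0.17, and the hormone gene Fgf21 by 4.15 ± 0.43 at 108 h. Of 13 immediate early genes, 9 rose at 108 h and 6 at 132 h (10 and 6 adjusted over the list alone), among them Fos (2.58 ± 0.40 and 2.56 ± 0.32). The list mean rose by 0.91 and 0.73 (exact permutation, adjusted p = 0.0233), with adjusted p = 0.401 at both times with an estimated correlation.

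Inflammatory and matrix genes rose and endothelial genes fell. Of 18 cytokine and chemokine genes, 5 rose and 1 fell at 108 h, also adjusted over the list alone (camera adjusted p = 0.0604), and 13 rose and 1 fell at 132 h (15 and 1 adjusted over the list alone). The list mean rose by 1.02 and 1.78 (exact permutation, adjusted p = 0.0233), and the 132 h list had adjusted p = 0.405 with an estimated correlation. Ccl2, which attracts monocytes, was at 1.72 ± 0.82 at 108 h (adjusted p = 0.0929) and rose by 3.32 ± 0.49 at 132 h. Without control replicate 5 the 108 h value was called (2.29, adjusted p = 0.0466). Nos2 fell by 1.41 ± 0.13 at 132 h. Of 22 fibroblast and matrix genes, 11 rose and 1 fell at 108 h and 18 rose at 132 h, with equal counts over the list alone, including Postn (0.68 ± 0.12 and 1.24 ± 0.13) and Lum (0.53 ± 0.11 and 1.42 ± 0.12). The list mean rose by 0.33 (exact permutation, adjusted p = 0.0441) and 0.74 (adjusted p = 0.0233), with adjusted p = 0.793 and 0.401 with an estimated correlation. The camera call at 108 h was lost without control replicate 2 (adjusted p = 0.0772) or CLA replicate 2 (0.0638). Of 13 endothelium genes, 11 fell at each time, also adjusted over the list alone, and the list mean fell by 0.57 and 0.73 (exact permutation, adjusted p = 0.0233), with adjusted p = 0.401 at both times with an estimated correlation. Kdr, a receptor for vascular growth factor, fell by 1.02 ± 0.12 and 1.21 ± 0.10.

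Of 19 interferon-response genes, 1 rose with CLA at 108 h and 15 at 132 h (0 and 16 adjusted over the list alone). At 132 h the list mean rose by 0.85 (exact permutation, adjusted p = 0.0233) with adjusted p = 0.894 with an estimated correlation. CLA replicate 3 at 132 h had a list mean of 6.48 log2 CPM against 4.16 to 4.59 in the other 4. The camera call was lost without it (median 0.45, adjusted p = 0.0604) and without control replicate 3 (adjusted p = 0.0587).

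Cell division genes rose with CLA: 33 of 33 at 108 h and 32 at 132 h (33 and 33 adjusted over the list alone). The list mean went from 2.83 ± 0.32 to 4.59 ± 0.25 log2 CPM at 108 h and from 2.66 ± 0.21 to 4.66 ± 0.20 at 132 h (exact permutation, adjusted p = 0.0233), with adjusted p = 0.401 and 0.281 with an estimated correlation. Mki67 rose from 37.2 ± 18.1 to 133 ± 24.4 CPM at 108 h (1.84 ± 0.33) and from 31.6 ± 11.1 to 135 ± 22.6 CPM at 132 h (2.09 ± 0.22). Of 21 luminal epithelium genes, 0 were called by edgeR at 108 h, also over the list alone, and 1 rose and 1 fell at 132 h (0 adjusted over the list alone), and the list mean was 0.25 lower and 0.17 higher (exact permutation, adjusted p = 0.820 and 0.873). CLA replicate 3 at 108 h had a luminal list mean of 0.70 log2 CPM against 3.01 to 3.41 in the other 4. A high skin signal was present in 2 of the 5 controls at 108 h and in 3 at 132 h, and in no CLA library. The near absence of luminal calls therefore does not exclude a rise with CLA. Pgr was at 2.27 ± 1.35 CPM with CLA and 2.50 ± 1.04 CPM in controls at 108 h (−0.15 ± 0.52, adjusted p = 0.838), and at 0.74 ± 0.55 at 132 h (adjusted p = 0.268). Of 18 estrogen-responsive genes, 5 rose and 3 fell at 108 h and 6 rose and 3 fell at 132 h, with equal counts over the list alone, and the list was not called (camera adjusted p = 0.600 and 0.507). Greb1 rose by 0.93 ± 0.35 at 132 h (adjusted p = 0.0299), a call lost without control replicate 1 (0.0768) or 4 (0.0691) or CLA replicate 3 (0.0533) or 5 (0.0764).

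**Figure D2:**
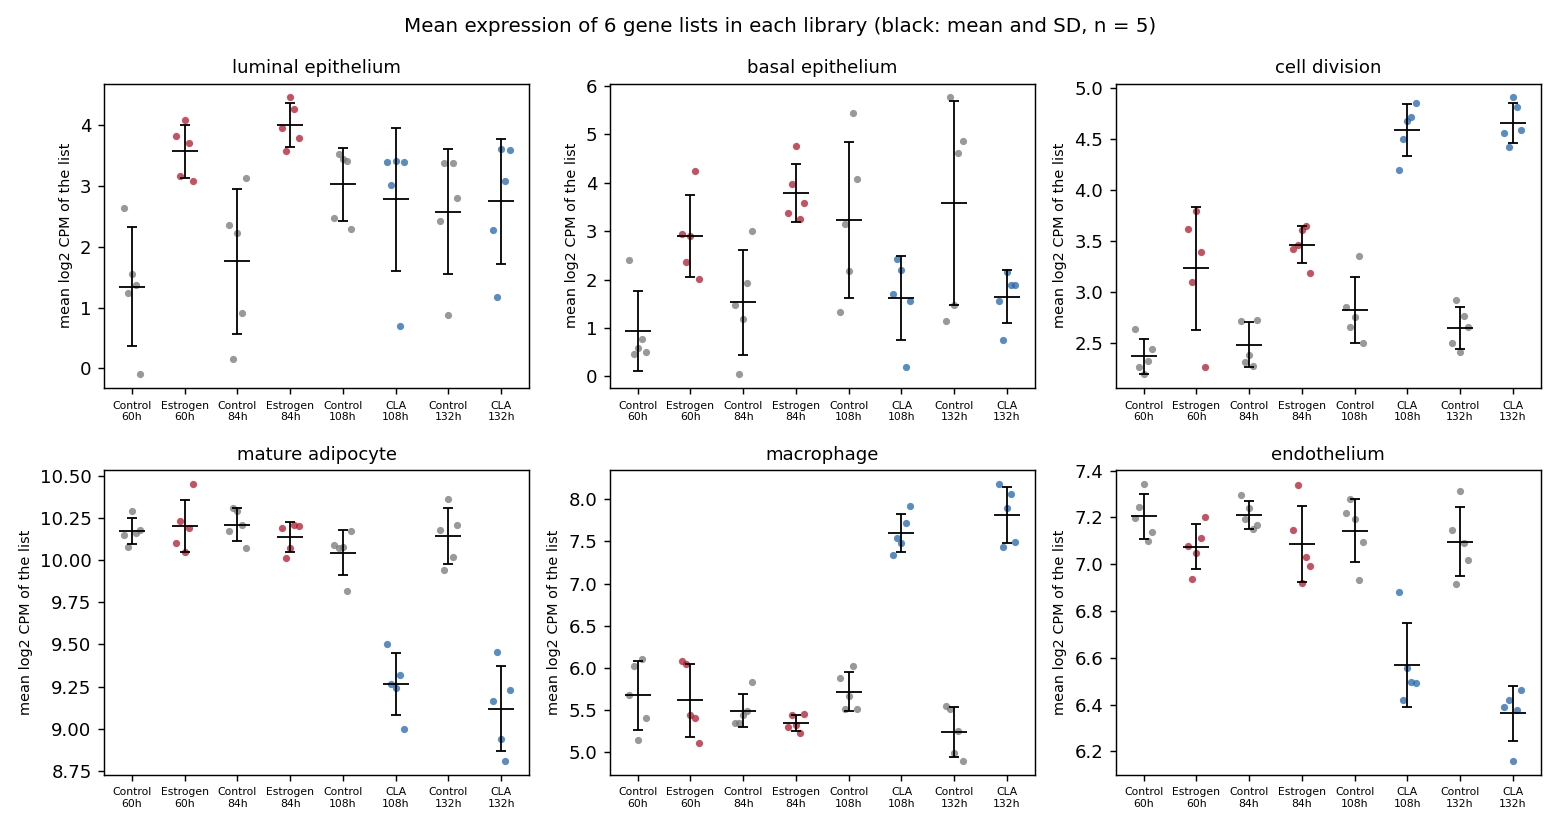
Mean log2 CPM of selected gene lists in each library, by group; points are single mice, with the mean and SD of 5 in black. Macrophage and cell division means are higher and the adipocyte mean lower in both CLA groups, and luminal means are higher in both estrogen groups.

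Basal epithelium and skin genes were lower with CLA. Of 15 basal genes, 10 fell at each time (13 and 10 adjusted over the list alone), including Trp63, the basal transcription factor gene (chromosome 16, 25683763 to 25892102, plus strand), by 2.53 ± 0.50 at 108 h. The list mean was 1.62 and 1.92 lower (exact permutation, adjusted p = 0.202 and 0.260), and camera called the list at 108 h (adjusted p = 0.0197, and 0.787 with an estimated correlation) and not at 132 h (0.0960). The 108 h call was lost without CLA replicate 3 (adjusted p = 0.0589). Among the largest falls at each time were genes of hair and stratified epithelium such as Krt71 (−6.68 ± 2.15 and −7.04 ± 2.04), whose control values were uneven (234.5 ± 378 CPM at 108 h). Of the skin and hair genes, 7 of 9 fell at 108 h and 10 of 11 at 132 h (8 and 10 adjusted over the list alone), while the list itself was not called (camera adjusted p = 0.182 and 0.273). These falls were measured against all 5 controls at each time, of which 2 at 108 h and 3 at 132 h had a high skin signal. Without the 9 libraries 4 basal genes were called lower at 108 h and 0 at 132 h by edgeR, and 1 rose at 132 h. Krt71 was not called at 108 h without control replicate 2 (−4.91, adjusted p = 0.0551) or without the 9 libraries (−3.53, adjusted p = 0.0761). At 132 h the sign turned without the 9 for Krt71 (1.44), Krt25 (2.14) and Krt73 (1.90), none of them called. Skeletal muscle genes were also lower, 10 of 15 at 108 h and 3 of 16 at 132 h (11 and 1 adjusted over the list alone), and camera did not call that list (adjusted p = 0.0959 and 0.219).

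**Figure D3:**
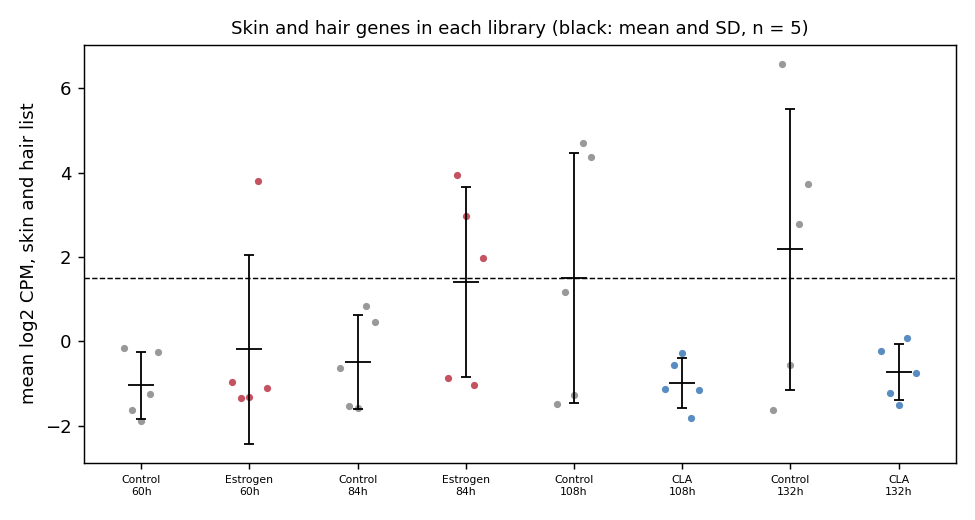
Mean log2 CPM of the skin and hair list in each of the 40 libraries, by group; the line marks the level of 1.5 above which 9 libraries lie. None of the 10 CLA libraries is above it.

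CLA changed 8261 of 17248 genes at 108 h, 4293 higher and 3968 lower, and 9613 of 17180 at 132 h, 4638 higher and 4975 lower. Limma on log2(RPKM + 0.1) gave 5247 higher and 2971 lower at 108 h and 6410 and 3097 at 132 h, where it moved the median log2 fold change of all genes from −0.03 to 0.12. Upper-quartile scaling gave 3592 higher and 4907 lower at 108 h and 4151 and 5618 at 132 h, and relative log expression scaling 4042 and 4297 at 108 h, so which direction held more genes depended on the processing. With the run of animal numbers as a term, the counts were 7777 and 8675, the latter with 4450 higher and 4225 lower. Without the 9 libraries with a high skin signal they were 7389 (4001 higher and 3388 lower) and 7325 (3750 and 3575). That left 3 controls at 108 h and 2 at 132 h. With the skin signal as a covariate, 7482 and 8460 genes were called, the latter with 4290 higher and 4170 lower. Among 16936 genes tested at both times, 6909 were called at both and 6908 of these had the same sign, against 4586 for independent lists, and fold changes had a Pearson correlation of 0.91 across genes. The difference between the effects at 132 h and 108 h was called for 0 genes by edgeR, with 2216 at an unadjusted p under 0.05. DESeq2 called 124, and limma on log2(RPKM + 0.1) and log2(RPKM + 1) called 16 and 20. Leaving out CLA replicate 4 of 108 h gave 137, CLA replicate 5 of 132 h 79, CLA replicate 1 of 132 h 5 and control replicate 2 of 108 h 1.

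**Figure D4:**
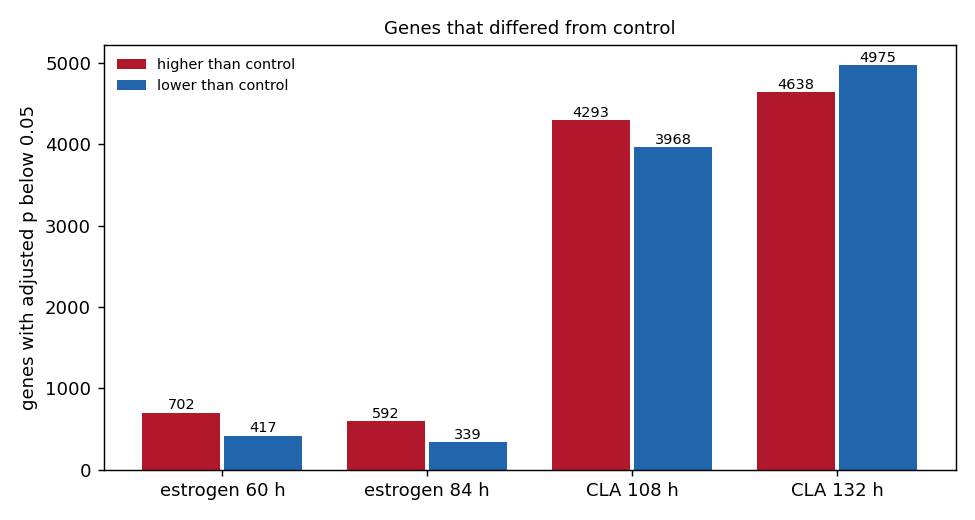
Number of genes called higher and lower in each of the 4 treatment comparisons, by edgeR with an adjusted p under 0.05. Counts are 1119 and 931 for estrogen and 8261 and 9613 for CLA.

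The effects of the agents were set against each other within each table. The CLA effect at 108 h differed from the estrogen effect at 60 h for 5532 of 17248 genes, 2964 higher with CLA and 2568 lower, and at the later times for 6536 of 17180, 3289 higher and 3247 lower. Upper-quartile scaling gave 2126 higher and 3544 lower for the early pair and 2740 and 4039 for the late pair, and limma on log2(RPKM + 0.1) 3573 and 1993, and 4297 and 2344. Large differences toward CLA were in Mmp12 (7.93 ± 0.93 and 9.28 ± 1.03) and Atp6v0d2 (6.69 ± 0.65 and 8.20 ± 0.58), and Gpnmb, a lysosomal glycoprotein gene of lipid-laden macrophages, differed by 5.78 ± 0.70 at the late pair. Large differences toward estrogen were in Krt17 (−8.76 ± 1.89 and −9.29 ± 1.58), Krt71 and other skin genes, and in Prom2 at the early pair (−6.12 ± 1.06). The early Krt71 difference was not called without estrogen replicate 5 of 60 h (−3.92, adjusted p = 0.371) or without the 9 libraries (−0.80). Without the 9 the late difference was not called for Krt17 (−2.77, adjusted p = 0.114), and it turned for Krt71 (5.39), Krt25 (6.06), Krt27 (3.64) and Krt72 (2.54), none of them called. The early differences of Prom2 and Krt17 were still called. Agent and sampling time changed together. All estrogen-treated mice also came from a run of animal numbers that held no control and no CLA-fed mouse. The values therefore do not separate agent, time and cohort.

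Genes called under both agents were counted with each agent's own controls. At 60 h and 108 h there were 591, of which 300 rose with both (175 for independent lists), 200 fell with both (95.9) and 91 moved in opposite directions. At 84 h and 132 h there were 643, of which 363 rose with both (160), 167 fell with both (98.2) and 113 were opposite. The late counts that rose and fell with both were 590 and 48 in limma on log2(RPKM + 0.1) (312 and 25.2 for independent lists). They were 424 and 105 with upper-quartile scaling (172 and 75.5) and 206 and 11 without the 9 libraries (60.2 and 4.49). In a fit of the 2 groups alone, 138 genes rose with both at the early pair against 126 for independent lists, so little of that excess was left. The excess of shared falls stayed, at 110 against 49.4. At the late pair that fit gave 388 that rose with both against 200, and 161 that fell against 88.3. Of the estrogen-called genes 52.8% and 69.1% were also called with CLA, against 47.9% and 56.0% of all genes. Fold changes had Pearson correlations of −0.21 and −0.38 across genes and Spearman correlations of 0.10 and 0.16. Without the 9 libraries with a high skin signal the Pearson correlations were 0.09 and 0.14, so both signs turned, and without estrogen replicate 5 of 60 h alone the early one was 0.07. The early count was lower without control replicate 2 (370), 3 (279) or 4 (238) or estrogen replicate 1 (165), 2 (371) or 5 (243) of 60 h. The late count was lower without control replicate 1 (318) or 5 (419) or estrogen replicate 3 (368) or 4 (393) of 84 h.

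Controls were compared across the 4 times, since the agents were sampled on different days. Luminal epithelium list means in controls were 1.34 ± 0.98 at 60 h, 1.76 ± 1.20 at 84 h, 3.03 ± 0.60 at 108 h and 2.58 ± 1.03 log2 CPM at 132 h. An F test of any difference called 2385 of 17852 genes, among them 11 of 11 skin and hair genes, 11 of 15 basal, 9 of 22 fibroblast and matrix and 6 of 21 luminal (11, 12, 12 and 9 adjusted over the list alone). The 5 controls with a high skin signal were all at 108 h and 132 h, the times with the higher luminal means. Limma on log2(RPKM + 0.1) called 1026, and 88 were called without the 9 libraries. Between the 3 runs of animal numbers in controls, 82 of 17204 genes differed, with 1862 at an unadjusted p under 0.05, and none differed without the 9 libraries or in limma on RPKM. That count was 35 without control replicate 2 of 108 h, 28 without replicate 3 and 17 without replicate 4 of 108 h, and 126, 197 and 12 without replicates 3, 4 and 5 of 132 h.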

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

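The tests that weigh explanations here were all chosen after the result was seen, whereas the search for libraries far from the other 4 of their group was set before the data were examined. It covered 43 measures in 8 groups, 344 groups of 5 values in all, and found 29, against about 1 in 20 groups by chance.

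Among library measures, CLA replicate 3 at 108 h had the highest total, 35.7 against 26.0 to 27.9 in the other 4 (in 1e6 counts), and estrogen replicate 1 at 60 h the lowest mitochondrial share, 6.16% against 7.87 to 8.31%. That estrogen library also had the lowest oxidative phosphorylation list mean (7.76 log2 CPM against 8.14 to 8.25). CLA replicate 3 at 108 h had the lowest list means of luminal epithelium (0.70 against 3.01 to 3.41) and of steroid receptors and sex steroid enzymes (2.15 against 2.52 to 2.63). Control replicate 1 at 84 h was lowest for the steroid list (2.08 against 2.38 to 2.45). Control replicate 1 at 60 h was highest for basal epithelium (2.40 against 0.46 to 0.77), for Krt8 (9.38 CPM against 0.266 to 2.73), for Krt14 (13.2 CPM against 0.385 to 1.72) and for Mki67 (31.6 CPM against 18.1 to 20.5). Control replicate 3 at 60 h was lowest for milk genes (0.65 against 1.95 to 2.42) and estrogen replicate 4 at 84 h highest (3.65 against 3.09 to 3.25).

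Interferon-response list means were far from the rest in 4 libraries: control replicate 2 at 60 h (6.86 log2 CPM against 3.67 to 4.37), estrogen replicate 5 at 60 h (4.02 against 3.37 to 3.55), control replicate 3 at 132 h (3.68 against 3.99 to 4.10) and CLA replicate 3 at 132 h (6.48 against 4.16 to 4.59). The last also had the lowest endothelium mean (6.16 against 6.38 to 6.46) and the highest Areg (2.79 CPM against 0.0925 to 0.786). Control replicate 2 at 60 h had the highest Ccl2 (10.3 CPM against 0.173 to 1.21), as had control replicate 5 at 108 h in its group (3.72 CPM against 0.707 to 1.24). Control replicate 4 at 84 h had the highest macrophage mean (5.84 against 5.35 to 5.49) and Adgre1 (59.8 CPM against 28.4 to 33.7). Control replicate 2 at 108 h had the lowest adipocyte mean (9.81 against 10.07 to 10.17) and the highest Areg (1.90 CPM against 0.0324 to 0.384). Estrogen replicate 5 at 60 h had the highest skin and hair mean (3.81 against −1.34 to −0.97) and skeletal muscle mean (2.97 against −0.60 to 0.29). CLA replicate 1 at 132 h had the highest muscle mean (2.05 against −0.17 to 0.08) and the lowest immediate early mean (4.64 against 4.94 to 5.00). Control replicate 1 at 132 h had the highest Krt14 (249 CPM against 2.65 to 63.5). Gm4876 was the gene whose estrogen effect differed between 84 h and 60 h, by −1.18.

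With CLA, adipocyte genes were lower and macrophage genes higher at both times. A lower share of adipocytes alone would raise the markers of every other cell type, and the endothelium list mean changed by −0.574 at the time with the smaller change. CPM values are relative, so this does not decide about a change in the mix of cells that includes more macrophages. The adipocyte median stayed at −0.656 or lower under 4 other scalings or units. These put the median log2 fold change of all genes between −0.08 and 0.12, too near 0 to undo the fall. They therefore do not decide about the scaling of libraries. Skin in some control libraries is argued against by a median of −0.80 or lower without the 9 libraries. Macrophage entry, with lower adipocyte expression or a lower adipocyte share, may account for the pattern, as a hypothesis found and tested on the same data.

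Basal epithelium genes were lower with CLA, and 5 of the 10 controls for CLA had a high skin signal. Skin in some control libraries could account for the fall at 132 h, where 0 of 10 called members were still called lower without the 9 libraries. With the skin signal as a covariate 1 of these 10, Krt17, was still called lower (−2.22, adjusted p = 0.0300, against −0.13 without the 9 libraries), so for Krt17 the cause stays open. At 108 h it could account for the 7 members no longer called lower. It is argued against as the whole cause for the 3 still called lower, Lama3 (−0.72), Lamb3 (−0.32) and Trp63 (−1.61). Leaving out the 9 also lowered the number of libraries, so part of the loss of calls may come from lower power.

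Luminal epithelium genes and Pgr were higher with estrogen. Skin in some estrogen libraries is argued against by a luminal median of 2.04 or higher without the 9 libraries. That median rests on 4 estrogen libraries at 60 h and on only 2 at 84 h. A larger share of luminal cells alone, as measured by the list mean, is argued against for Pgr. It rose beyond that mean by 2.33 log2 units at 60 h and 2.86 at 84 h (exact permutation, adjusted p = 0.00794, the smallest possible with 5 against 5). Krt8, a member of the list, also rose by more than the mean, so the mean may understate the luminal share. Nor can it separate more cells with Pgr from more Pgr per cell. The estrogen mice being 1 cohort of animal numbers cannot be told apart from estrogen, since no control lies in that run. Of the 337 genes called at both times and tested between control runs, 0 also differed there, against 82 (0.486%) of the other genes tested (Fisher's exact test, p = 0.414), and these runs may not show what the fourth was like.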

How the results depend on the processing

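Tests without the 9 libraries with a high skin signal, with that signal as a covariate, and of list means by exact permutation were chosen after seeing the data. Counts for CLA at 108 h and at 132 h, and for the difference between agents at 108 h and 60 h, stayed within 1.5 times under each alternative run. Similar counts can hold different genes. Limma on log2(RPKM + 0.1) called 868 and 977 genes for estrogen at 60 h and 84 h, of which 663 and 608 were main calls. For CLA it called 8218 and 9507, of which 6935 and 7497 were main calls. DESeq2 kept 1114 of the 1119 main estrogen calls at 60 h and all 931 at 84 h. Counts that moved beyond 1.5 times follow, and the cause was not tested except where fewer libraries or a larger number of genes tested enter by construction. DESeq2 gave 1863 genes for estrogen at 60 h, 1611 at 84 h, 17 for the difference between estrogen times, 124 for that between CLA times, 191 for control runs of animal numbers, and 1022 and 1105 for the early and late genes shared by both agents. Without a filter, estrogen at 60 h gave 593, the CLA time difference 2 and the early shared genes 312. Limma on log2(RPKM + 0.1) gave 0 for the estrogen time difference, 16 for the CLA one, 1026 for controls across times and 0 for control runs. Limma on log2(RPKM + 1) gave 697 for estrogen at 60 h, 20, 933, 0 and, for early shared genes, 384. A fit of the 2 groups alone gave 742 at 60 h and 304 early shared genes. Without the 9 libraries, estrogen gave 697 and 303, the late difference between agents 3453, the estrogen time difference 0, controls across times 88, control runs 0, and shared genes 335 and 225. With the covariate, estrogen at 84 h gave 594, the CLA time difference 3, controls across times 716 and late shared genes 383.

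Leaving out each library gave 316 to 1210 genes for estrogen at 60 h, 443 to 1152 at 84 h, 7637 to 8367 for CLA at 108 h and 8984 to 9557 at 132 h. The differences between agents ranged from 5020 to 5918 and from 6004 to 6768, the estrogen time difference from 1 to 2 and the CLA one from 0 to 137. Controls across times gave 1703 to 2661, control runs 12 to 197, and shared genes 165 to 718 and 318 to 793.

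Signs turned in these cases, none of them called. Among the called basal genes, without the 9 libraries, CLA at 132 h gave Dsc3 1.14, Sfn 1.04, Col17a1 0.68, Krt15 0.62, Krt5 0.57, Krt6a 0.27 and Trp63 0.02, and at 108 h Krt6a 0.42. With the covariate, 108 h gave Dsc3 0.54, Krt15 0.17 and Krt6a 0.12. Without the 9 libraries, CLA at 132 h gave Krt27 0.41, Krt71 1.44, Krt25 2.14, Krt73 1.90, Krt28 0.67, Gjb2 0.65 and Krt14 1.09, and the late difference between agents gave Krt72 2.54, Krt27 3.64, Krt71 5.39 and Krt25 6.06. With the covariate, the early difference of Krt71 was 1.23, and the late ones of Krt71 and Krt25 were 0.61 and 0.25. The fibroblast and matrix median for estrogen at 84 h was 0.0058 without the 9. All 43 list calls by camera (10, 10, 11 and 12) were lost with an estimated correlation (smallest adjusted p 0.281). Of 100 list tests, 13 lost and 6 gained a call under exact permutation, and 8 lost and 3 gained it with fry. Named genes lost their call with the sign kept in 40 cases without the 9 libraries and in 27 with the covariate. A further 11 and 3 cases lost it with the sign turned.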

Other observations

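The tests and gene lists below were all chosen after the result was seen, except the fixed lists of lymphocyte, blood, nerve, steroid and cholesterol genes.

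With CLA, genes of lipid-associated macrophages, lysosomes and the antioxidant response were higher. Of 13 lipid-associated macrophage genes, 10 rose and 1 fell at each time, with list means 2.09 and 2.72 log2 units higher. Of 19 lysosome genes, 17 rose at 108 h and 18 at 132 h (0.71 and 0.82 higher), and of 13 antioxidant genes, 9 and 8 rose (0.86 and 0.80 higher). These 3 lists were drawn up after the results were seen, and the first holds Mmp12, Atp6v0d2 and Itgax, which had already been named for their rise, so no test is given for them. Among the fixed lists, the steroid receptor and enzyme mean was higher with estrogen by 0.52 and 0.60 (exact permutation, adjusted p = 0.0233). Of its tested members, 1 of 7 rose at 60 h and 1 of 8 at 84 h, Pgr in each case, with a median log2 fold change of 0.01 and −0.11 and a camera adjusted p of 0.796 at both times. No lymphocyte, blood or cholesterol synthesis gene was called with estrogen by edgeR, also adjusted over the list alone, and 1 nerve sheath gene rose at 84 h. Camera called the cholesterol synthesis list higher with estrogen at 84 h, a call lost without control replicate 4 (adjusted p = 0.179). Its list mean was 0.27 higher (exact permutation, adjusted p = 0.416). With CLA, 2 of 20 lymphocyte genes rose at 108 h and 4 fell at 132 h (2 and 0 adjusted over the list alone), and 2 of 7 blood genes rose at each time, also adjusted over the list alone. Cholesterol synthesis genes went both ways, 4 up and 3 down at 108 h and 2 up and 3 down at 132 h (1 and 1, and 2 and 3, adjusted over the list alone).

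Cell division genes were higher with CLA, and the dividing cells are not identified by the labels. For dividing luminal cells, the cell division and luminal list means across the 10 CLA libraries had r = 0.141 (permutation p = 0.700, rho = 0.321 with p = 0.366, r = 0.172 without 2 libraries, −0.27 and 0.757 within times, 0.44 in the first run of animal numbers). For dividing macrophages, r was 0.649 (permutation p = 0.0413, adjusted p = 0.0619 over 9 relations, rho = 0.624 with p = 0.0608, r = 0.893 without 2 libraries, 0.516 and 0.860 within times, 0.828 in the first run). The closest relation was with the mature adipocyte list, r = −0.854 (permutation p = 0.00138, adjusted p = 0.0038 over 9 relations, rho = −0.794 with p = 0.00916, r = −0.832 without 2 libraries, −0.926 and −0.864 within times, −0.825 in the first run), and it was −0.868 in estrogen and −0.818 in control libraries. There it was uneven: within times r ran from −0.995 to −0.235 in estrogen and from −0.963 to −0.306 in control libraries, within runs from −0.962 to −0.293 in controls, and the estrogen rho was −0.644 (permutation, adjusted p = 0.0894). The luminal relation was r = 0.794 in estrogen (permutation, adjusted p = 0.0038) and 0.736 in control libraries (adjusted p = 0.00054), neither of which speaks to the CLA libraries. Within times the luminal r ran from 0.681 to 0.897 in estrogen and from 0.328 to 0.875 in control libraries. The permutation of controls mixed the 4 times, and with group means removed their r was 0.579. The other runs held too few CLA libraries. Neither explanation is excluded, since the interval of the first r ran from −0.536 to 0.708 and list means share the scaling of a library, and dividing macrophages may be 1 source among others.

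Other splits of the same libraries into groups of the same sizes, 100 per result with the real one included, were fitted for each count of genes (chance as the explanation). Chance can be excluded for estrogen at 60 h (1119 genes, highest other 162) and 84 h (931, highest other 10), for CLA at 108 h (8261, highest other 4756) and 132 h (9613, highest other 5037) and for controls across times (2385, highest other 861), each with 1 split as large, the real one. For the differences between agents, treated libraries and controls were mixed separately. A split that left the treated libraries nearly in place could thus keep much of the difference between agents. The splits therefore do not decide about chance for the late difference (6536, highest other 5967, 1 split). The same holds for the early difference (5532, highest other 6052, 2 splits). For control runs (82, highest other 94), 2 of 100 splits were as large, the real one included. There 1 other split called more genes, so chance is not excluded. The control-run count was also 0 without the 9 libraries and in limma on RPKM. For genes shared by both agents (591 and 643, highest other 0 in each) the splits decide nothing, since the median split called 0 genes under either agent alone and left no overlap to count. Nor do they decide for the CLA time difference (0 genes, highest other 453, 100 splits), as every split calls at least 0. Chance cannot be excluded for the estrogen time difference (1 gene, highest other 14, 5 splits). Splits calling many more genes than the real one in both time differences point to a structure of the samples, and what it is was not tested. Nor can chance be excluded for the number of lists called by camera: as many were called in 70 and 52 of 100 splits for estrogen (10 lists at each time, highest other 19 and 18) and in 62 and 63 for CLA (11 and 12 lists, highest other 19 and 18).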
